A study of Mus musculus with 6 samples.

How the data were processed

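The study measured where biotinylated TRβ1 was bound in mouse liver by ChIP-seq after capture on streptavidin agarose. Per the labels' protocols, the mice were 9 to 10 weeks old, chromatin was crosslinked with disuccinimidyl glutarate and formaldehyde, and it was sheared by sonication. The labels describe 6 samples: 3 ChIP samples (GFP PTU, TRb PTU and TRb T3) and the 3 matching input samples, for which no peak list was used here. Each sample was assigned to its group from its title. There was 1 library per condition, and the labels do not say how many animals went into a library.

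The deposited files are peak lists, 1 per ChIP sample, giving a chromosome, a start, an end, a name and a score for each peak. The submitters' processing notes name Bowtie, SAMtools and MACS2 and the genome build mm9. Versions, settings, the control library used for calling and any filtering are not given in the sources used here. The score in the deposited lists is the authors' peak caller's value for each peak. Its lowest value was 2.00 to 2.02 in the 3 lists, and the files do not say which statistic it is, so it was used only to rank or filter peaks within a list or within that list's members of a set of pairs. The lists differed in their narrowest peak (51 bp in GFP PTU, 134 bp in TRb PTU and 132 bp in TRb T3), which can move overlaps and covered lengths. The files hold no read counts, so depth is unknown and a difference in the number of peaks cannot be separated from a difference in depth.

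All sequences in the files were kept for overlaps, including unplaced and mitochondrial sequence (88 TRb PTU, 98 TRb T3 and 1 GFP PTU peaks outside chromosomes 1 to 19 and X). Comparisons by chromosome and by window used chromosomes 1 to 19 and X. Peaks overlapped if they shared at least 1 bp. A TRb PTU peak with no overlapping TRb T3 peak was called PTU-only, the reverse T3-only, and all others shared. Shares were given exact (Clopper-Pearson) 95% binomial intervals over peaks. Random overlap was the mean of 100 placements of the other list, each peak keeping its chromosome and width and falling between the first and last peak of that chromosome. The ratio of peak numbers per chromosome had an exact 95% interval from the binomial share, which treats the peaks of both lists as independent counts. Windows were 500 kb long on a grid from position 1 of each chromosome, and peaks were assigned by their midpoint. Ranks were compared between lists only among the 27010 pairs in which each peak overlapped a single peak of the other list, ranked again within that set so that both rankings had the same length. Positions are printed 1-based. No p-value is given between conditions, because peaks of 1 library are not replicates.

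The peaks named are, by a rule set before the data were examined, the 10 highest-scored shared (by TRb T3 score), PTU-only and T3-only peaks and the 5 highest-scored GFP peaks. The minimum overlap, the score filter, equal numbers of peaks, removal of peaks at GFP sites and the local shift were also planned then. Peaks are named by coordinate because that rule named them by gene only with an mm9 annotation. The windows and further alternatives were chosen later. The location of peaks relative to genes, the fixed gene lists and the search for direct repeats of the receptor half-site were planned and not run, because no mm9 annotation or sequence was used here. The gene table at hand was for GRCm38, whose coordinates do not apply to mm9.

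The overlap code was tested on simulated data made from the 46092 TRb T3 peaks, where shares of 30.2, 59.8 and 90.0% made were found as 30.2, 59.8 and 90.0%. Kept peaks were moved by less than their width and the added peaks lay on a separate made-up sequence. The found shares were thus nearly fixed in advance, and random overlap was not tested. The code for neighbouring peaks was tested on the 46092 TRb T3 peaks, where labels in runs of 5 gave 90.0% same-label neighbours and independent labels gave 50.1%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.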

Results

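Binding of tagged thyroid hormone receptor β1 (TRβ1) to liver chromatin was mapped in mice with and without injection of thyroid hormone. TRβ1 is the nuclear receptor through which the liver responds to triiodothyronine (T3), the active thyroid hormone. The mice carried the biotin ligase BirA, which attaches biotin to a tagged protein, and received an adenovirus encoding either GFP alone or GFP together with biotinylated TRβ1. All mice were fed propylthiouracil (PTU), an inhibitor of thyroid hormone synthesis, for 3 weeks and then injected with saline or T3 for 4 days. Biotinylated TRβ1 was captured on streptavidin and the bound DNA was sequenced (ChIP-seq). There were 3 ChIP samples, 1 library per condition: GFP alone with PTU and saline (GFP PTU), TRβ1 with PTU and saline (TRb PTU), and TRβ1 with PTU and T3 (TRb T3). The read depth behind the peak lists is unknown, and with no replicates no test between conditions was made. Shares carry exact 95% binomial intervals over peaks, which cover counting error only and not the variation between animals. All positions are on mm9, and peaks are given by coordinate because no gene annotation of that build was used.

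The first comparison addressed how much of the captured signal depended on TRβ1. Livers with tagged TRβ1 gave many more peaks than livers with GFP alone. The GFP PTU list held 107 peaks covering 12207 bp. The TRb PTU list held 51992 peaks covering 13.1 Mb, 486 times as many peaks, and the TRb T3 list held 46092 peaks covering 10.4 Mb, 431 times as many. The median peak width was 70 bp in GFP PTU against 210 bp for TRb PTU and 193 bp for TRb T3. The narrowest peaks measured 51, 134 and 132 bp respectively. Whether the 3 lists were called with the same settings is not given in the sources used here, and both the number and the width of peaks depend on those settings. The score of a peak is the value of the authors' peak caller and serves here to rank or filter peaks within a list, so scores printed from different lists are not compared in size.

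The strongest GFP peak lay on chromosome X at 103382090 to 103382418 (score 35.33), followed by chromosome 17 at 56339440 to 56339506 (31.14) and chromosome 5 at 60434082 to 60434256 (28.05). Next came a peak on chromosome 14 at 18758368 to 18759802 (26.72) and a peak on chromosome 2 at 22443741 to 22443795 (22.31). The first 4 of these overlapped peaks in both TRβ1 lists, and the peak on chromosome 2 overlapped a TRb T3 peak alone. GFP peaks were crowded in a few places, with 8 on chromosome 2 between 22443280 and 22445682, 3 on chromosome 14 between 18758368 and 18762336, and 3 on chromosome X between 103382090 and 103399429.

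Few TRβ1 peaks lay at sites also called in GFP livers. With only 107 GFP peaks these shares had to be low, so they do not measure the background among TRβ1 peaks. A GFP peak overlapped 84 TRb PTU peaks (0.162%, interval 0.129 to 0.200%) and 47 TRb T3 peaks (0.102%, interval 0.0749 to 0.136%). Seen from the GFP list, 92 of its 107 peaks were overlapped by a TRb PTU peak (86.0%, interval 77.9 to 91.9%) and 52 by a TRb T3 peak (48.6%, interval 38.8 to 58.5%). Of the 107 GFP peaks, 47 met a peak in both TRβ1 lists, 45 in TRb PTU alone, 5 in TRb T3 alone and 10 in neither. TRβ1 peaks placed at random on the same chromosomes overlapped 0.579% of GFP peaks for TRb PTU and 0.467% for TRb T3, as means of 100 placements. With TRβ1 peaks at or above the median score of their list, 60 GFP peaks were overlapped by TRb PTU and 33 by TRb T3.

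The second comparison addressed whether TRβ1 occupied the same sites with and without injected T3. More than 50% of each list was found in the other. TRb T3 peaks overlapped 28010 of the 51992 TRb PTU peaks (53.9%, interval 53.4 to 54.3%), and TRb PTU peaks overlapped 28276 of the 46092 TRb T3 peaks (61.3%, interval 60.9 to 61.8%). Random placement of the other list gave 0.934% and 1.04%, so the observed shares were 57.7 and 59.1 times higher. When each peak of the other list was only moved by up to 50 kb, which keeps it in its neighbourhood, the overlapped shares were 3.24% and 3.64%. The remaining 23982 TRb PTU peaks were PTU-only and the remaining 17816 TRb T3 peaks were T3-only. Where a peak of one list met a single peak of the other, which held for 27010 pairs, the midpoints differed by a median of 18 bp. Scores of these pairs correlated across peaks with a Spearman coefficient of 0.51, and peaks within a library are not independent replicates.

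The highest-scored shared peak, by its TRb T3 score, lay on chromosome 7 at 52130191 to 52130584. It was the highest-scored peak of both lists, with a score of 579.09 in TRb T3 and 615.60 in TRb PTU. The next shared peaks were on chromosome 10 at 7493956 to 7494504 (TRb T3 score 490.99, TRb PTU score 400.67) and on chromosome 18 at 51621478 to 51622067 (486.19 and 174.29). The other 7 of the 10 highest shared peaks began at position 153738664 of chromosome 2, 31292818 of chromosome 3, 31451797 of chromosome 14, 41673120 of chromosome 10, 107255851 of chromosome 8, 128969922 of chromosome 2 and 134886090 of chromosome 6, with TRb T3 scores from 410.24 to 441.70. Their TRb PTU scores ran from 9.01, at the site on chromosome 10, to 311.15, at the site on chromosome 8.

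Overlap rose with peak score in both lists. In the lowest score decile, 23.5% of TRb PTU peaks (interval 22.4 to 24.7%) and 38.7% of TRb T3 peaks (interval 37.3 to 40.1%) were overlapped. In the highest decile the shares were 94.4% and 91.3%, which left 5.58% of these TRb PTU peaks PTU-only (interval 4.97 to 6.24%) and 8.70% of these TRb T3 peaks T3-only (interval 7.90 to 9.55%). PTU-only peaks had a median score of 12.62 against 32.09 for the other TRb PTU peaks, and T3-only peaks had 14.95 against 30.27 for the other TRb T3 peaks. Peaks of a single list were also narrower, with a median of 184 against 240 bp in TRb PTU and 170 against 212 bp in TRb T3.

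**Figure D1:**
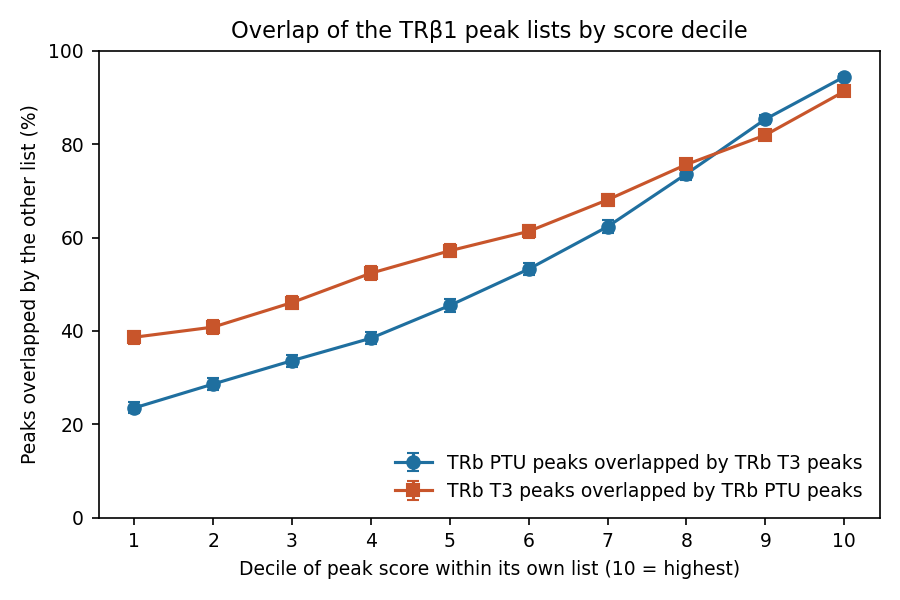
Share of peaks overlapped by the other TRβ1 list (y axis, percent) against the decile of peak score within the own list (x axis, 10 is the highest), for TRb PTU (circles) and TRb T3 (squares), with exact 95% binomial intervals as bars. The shares rise from 23.5% and 38.7% in the lowest decile to 94.4% and 91.3% in the highest.

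Some strongly scored sites were nevertheless called in 1 condition alone. The highest-scored T3-only peak lay on chromosome 12 at 14216623 to 14217105 (score 342.89), with the nearest TRb PTU peak midpoint 140951 bp away. The next T3-only peaks were on chromosome 16 at 81363364 to 81363736 (323.75), on chromosome 1 at 187794530 to 187795135 (299.73), on chromosome 12 at 43329257 to 43329580 (287.96) and on chromosome 4 at 61462388 to 61462974 (276.81). The other 5 of the 10 began at 57007352 on chromosome 19, 44017801 and 76971532 on chromosome 16, 168172549 on chromosome 2 and 122072798 on chromosome 3. All 10 had scores of at least 262.32. The peak on chromosome 4 lay within the block of T3-only peaks described below. Its nearest TRb PTU peak midpoint was 4728 bp away, the shortest distance of the 10.

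The highest-scored PTU-only peak lay on chromosome 19 at 42317111 to 42317391 (score 246.97), 90619 bp from the nearest TRb T3 peak midpoint. It was followed by peaks on chromosome 9 at 20365499 to 20365831 (244.18), on chromosome 6 at 99616840 to 99617074 (235.50), on chromosome 11 at 75073808 to 75074076 (227.12) and on chromosome 6 at 89247291 to 89247650 (226.34). The other 5 of the 10 began at 112054133 on chromosome 13, 76024385 on chromosome 15, 86950291 on chromosome 7, 193780124 on chromosome 1 and 124284887 on chromosome 5, with scores from 196.45 to 218.30. The site on chromosome 1 had a TRb T3 peak midpoint 706 bp away, and at the other 9 sites the distance was 1495 bp or more.

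The balance between the conditions differed between chromosomes. Over chromosomes 1 to 19 and X, TRb PTU had 1.13 times as many peaks as TRb T3. The ratio was highest on chromosome 11, with 4101 against 3090 peaks (1.33, interval 1.27 to 1.39), and next on chromosome 17 (1.28, interval 1.20 to 1.36). It was lowest on chromosome 13, with 2030 against 2072 peaks (0.980, interval 0.921 to 1.04), and chromosome 18 (0.989, interval 0.921 to 1.06). For 4 of the 20 chromosomes the interval lay above the common ratio and for 6 it lay below. These intervals treat all peaks as independent counts, although many sites were in both lists, so this tally is a description only. PTU-only peaks made up 49.8% of TRb PTU peaks on chromosome 11 and 43.8% on chromosome 13, while T3-only peaks made up 32.3% and 44.5% of TRb T3 peaks there. Chromosome X held the fewest peaks per Mb up to the last peak, 3.65 in TRb PTU and 3.53 in TRb T3, against 33.7 and 25.4 on chromosome 11.

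**Figure D2:**
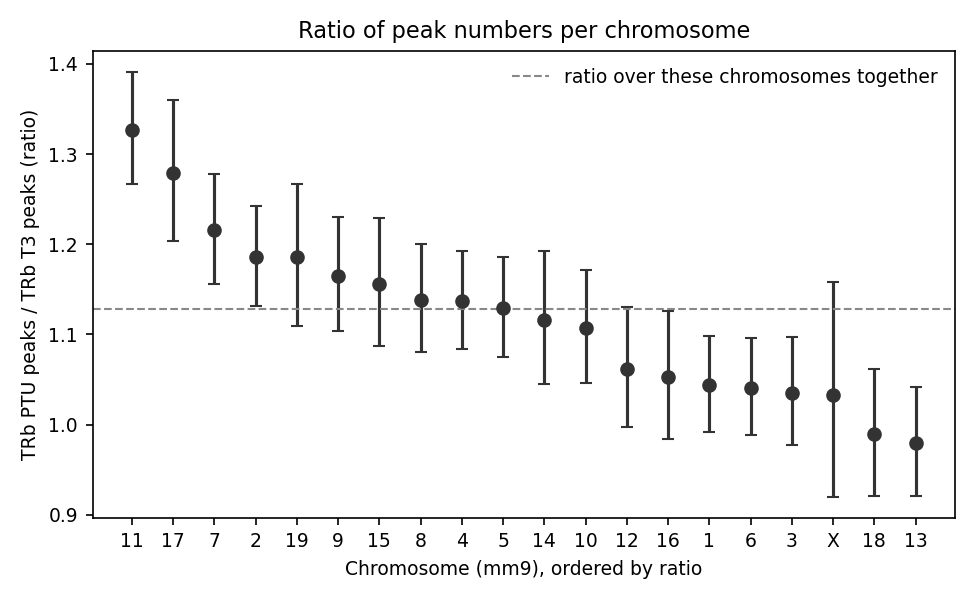
Number of TRb PTU peaks divided by the number of TRb T3 peaks (y axis) on each chromosome (x axis, mm9, ordered by the ratio), with exact 95% intervals as bars and the common ratio of 1.13 as a dashed line. Chromosome 11 lies highest at 1.33 and chromosome 13 lowest at 0.980.

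Peaks of a single condition were also concentrated in particular regions. Windows of 500 kb were examined after the values had been seen, and those with the largest differences are given. The 3 windows with the largest excess of T3-only peaks were adjacent and formed a block on chromosome 4 from 60000001 to 61500000. This block held 146 TRb T3 peaks, of which 105 were T3-only, and 42 TRb PTU peaks, of which 0 were PTU-only. The GFP list had 0 peaks there. Scores were ranked in each list among the same 27010 single pairs, of which 48.9% ranked higher in TRb T3. Of the 40 such pairs in the block, all 40 ranked higher in TRb T3, by a median of 33.2 percentile points (range 2.38 to 84.0). In 547 other windows of 1.5 Mb with at least 20 pairs, the share ranking higher in TRb T3 ran from 16.7 to 87.0%. TRb T3 peaks in the block recurred at a spacing of 5000 to 5250 bp, which was 6.58 times as frequent as the mean of spacings between 2 and 20 kb, against a median of 2.40 and a maximum of 2.77 times in 18 other windows with at least 100 TRb T3 peaks. A looser count of regularly spaced peaks gave 9.59% in the block and up to 8.55% in those windows. Whether the pairs and peaks of the block are separate observations is not known. With peaks at or above the median score in both lists, the block had 56 T3-only peaks, of which 45 were T3-only with all peaks and 11 were shared peaks whose TRb PTU partner fell below the median. The next T3-only windows were on chromosome 13 from 34000001 to 34500000, with 38 T3-only and 8 PTU-only peaks, on chromosome 16 from 76000001 to 76500000, with 25 and 2, and on chromosome 15 from 59500001 to 60000000, with 21 and 0. Tied with the last of these by its excess was chromosome 4 from 11500001 to 12000000, outside the block, with 23 and 2.

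**Figure D3:**
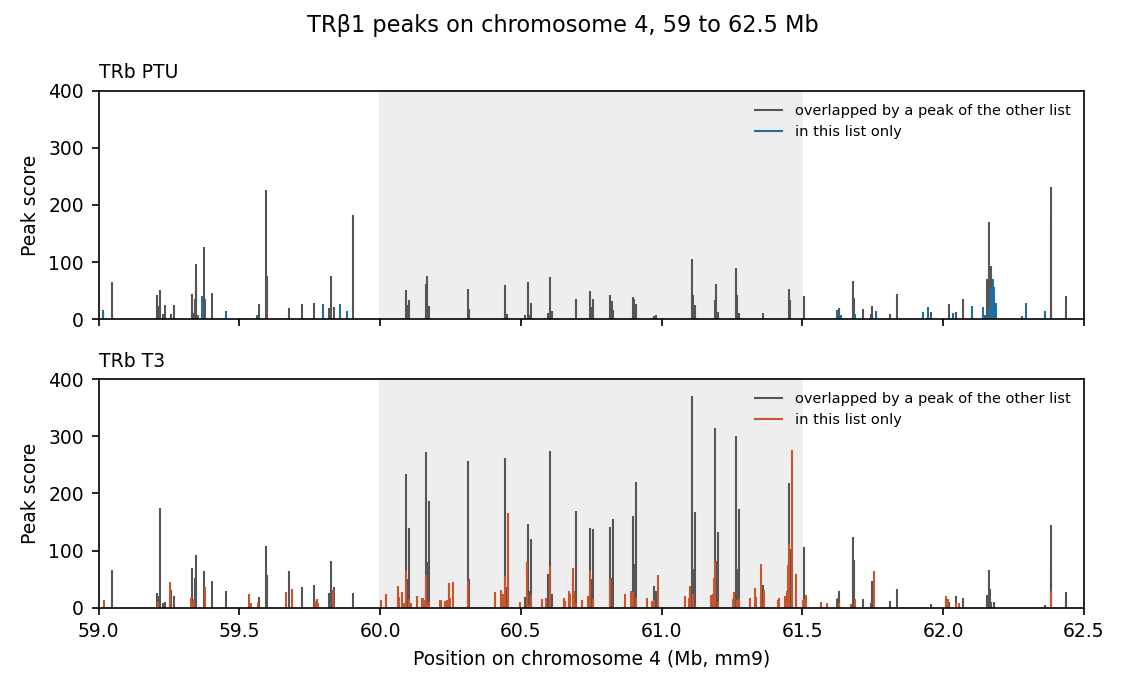
Peaks on chromosome 4 from 59 to 62.5 Mb (x axis, mm9) in TRb PTU (upper panel) and TRb T3 (lower panel). Each line is a peak drawn to its score in its own list (y axis), coloured when the other list had no overlapping peak, and the shaded block holds 105 T3-only and 0 PTU-only peaks.

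The windows with the largest excess of PTU-only peaks lay on chromosome 10 from 80500001 to 81000000, with 59 PTU-only and 3 T3-only peaks, and on chromosome 11 from 120000001 to 120500000, with 57 and 3. They were followed by chromosome 10 from 79500001 to 80000000, with 55 and 4, and chromosome 17 from 56000001 to 56500000, with 49 and 5. Tied with the last of these by its excess was chromosome 10 from 80000001 to 80500000, with 50 and 6. These windows also held 42, 35, 50, 41 and 50 shared TRb PTU peaks. All windows come from 1 library per condition, so the differences were not compared with the spread between animals. With peaks at or above the median score in both lists, the largest excess in a window was 20 T3-only peaks (38 with all peaks) and 33 PTU-only peaks (56 with all peaks), counting also peaks whose partner fell below the median.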

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

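Alternatives for gene location, gene lists and receptor elements were not run, nor was the test of peaks at Thrb exons, because no mm9 annotation or sequence was used here. No paired analysis was possible because each condition had 1 library. Values below are for TRb PTU and then TRb T3, and the choices of 1 kb, of equal numbers for GFP sites, and all those for chromosomes, windows and the block were made after seeing the data. The overlapped share (53.9 and 61.3%) was 53.2 and 60.2% for midpoints within 200 bp, 61.1 and 68.0% within 1 kb, 57.7 and 58.4% with equal numbers, 53.1 and 60.1% for peaks at or above the median score in both lists, and 73.8 and 75.7% with that filter on the queried list alone. The top decile (94.4 and 91.3%) was 92.6 and 89.6% within 200 bp and 87.1 and 84.5% with the filter on both lists. For TRb T3 it was 90.4% with equal numbers and 92.2% within 1 kb. Random overlap (0.934 and 1.04%) became 3.24 and 3.64% with the local shift. Restricting the TRβ1 lists to scores at or above their median left 60 and 33 GFP peaks overlapped (92 and 52 before) and 27 TRb T3 peaks at GFP sites (47 before). Equal numbers gave ratios of 1.17 on chromosome 11 (1.33 before) and 0.876 on chromosome 13 (0.980 before), with a common ratio near 1 by construction. The median filter on both lists gave 56 T3-only peaks in the block on chromosome 4 (45 of the 105 before and 11 shared before) and a largest window excess of 20 T3-only (38 before) and 33 PTU-only peaks (56 before); it removes peaks and also makes shared peaks single by removing their partners. Removing peaks at GFP sites moved none of the shares, ratios or excesses out of their intervals or by over 1.5 times. It took out only 84 of 51992 and 47 of 46092 peaks, so it could hardly move them and does not show how much background matters. Unknown depth limits every comparison of peak numbers.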

Other observations

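The tests on neighbouring peaks of the same class, GFP sites, the block on chromosome 4 and the rank shift of shared pairs were chosen after the patterns were seen. The tests on the top score decile and on peak-dense windows were set before their results were seen.

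The 5 fullest windows of 500 kb differed in part between the TRβ1 lists. In TRb PTU, 3 of the fullest windows of 500 kb were adjacent on chromosome 10, from 79500001 to 81000000, with 105, 100 and 101 peaks against a mean of 9.84 per window, the 100 being tied with a window on chromosome 5. Of those peaks, 50, 50 and 42 were overlapped by TRb T3 peaks, so these windows were rich in TRb T3 peaks as well. In TRb T3, the fullest was on chromosome 8 from 129000001 to 129500000, with 93 peaks against a mean of 8.72. The TRb PTU count of that window is not given here. The window on chromosome 5 from 125500001 to 126000000 ranked among the 5 fullest of both lists, with 100 and 80 peaks.

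The mitochondrial sequence held 13 TRb PTU peaks covering 8694 bp and 2 TRb T3 peaks covering 16089 bp, the wider of them 12514 bp long, and 0 GFP peaks. The highest mitochondrial scores, 4.82 in TRb PTU and 8.96 in TRb T3, lay below the lower quartiles of their lists (10.55 and 12.04). A region on chromosome 1, at 24618652 to 24622644 in GFP PTU and picked after its values were seen, was called in all 3 lists. Its highest score was low in GFP PTU (3.31, lower quartile of the list 3.56) and in TRb PTU (2.82, lower quartile 10.55). In TRb T3 it was 64.38, above the upper quartile of 46.41. The unplaced Y sequence held 8 TRb PTU peaks, all overlapped by TRb T3 peaks, and 31 TRb T3 peaks, of which 23 were T3-only.

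The first pattern is the large number of peaks found in a single TRβ1 list. A candidate explanation is calling noise near the threshold, which would leave almost no single-list peaks among the highest scores. PTU-only peaks made up 5.58% of the top TRb PTU decile and T3-only peaks 8.70% of the top TRb T3 decile, between the limits set in advance (under 5% if noise, at least 20% if not), so this test leaves the bulk of weaker peaks open. Neighbouring single-list peaks 10 to 100 kb apart, without the block on chromosome 4, were of the same class in 58.7% of 18820 pairs, against at most 52.9% in 1000 shuffles within chromosomes, which argues against independent random loss of calls as the whole cause. A preference of a library for peak-dense regions stays open. Over 1726 windows, the PTU-only share rose with the number of shared peaks with a Spearman correlation of 0.13. PTU-only peaks made up 54.9% of single-list peaks in the window quintile with the fewest shared peaks and 64.7% in that with the most. Base composition was not tested because no mm9 sequence was used here. A change of TRβ1 binding with T3, differences between animals and library bias cannot be told apart, since each condition had 1 library.

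The second pattern is that GFP peaks met TRb PTU peaks (92 of 107) more often than TRb T3 peaks (52 of 107). Fragments of TRb PTU carried over into the GFP library would fall on the strongest TRb PTU peaks, yet the TRb PTU peaks met had a median score percentile of 65.6 (quartiles 40.4 and 84.6). The greater length of the TRb PTU list does not account for it by itself, because an equal number of its highest-scored peaks still met 82 GFP peaks. That cut does not equalise depth or calling settings, which are unknown, so a part for them stays open. Of the 84 TRb PTU peaks at GFP sites, 39 were PTU-only (46.4%, against 46.1% in the whole list), while 3 of the 47 TRb T3 peaks at GFP sites were T3-only (6.38%, against 38.7%). The GFP and TRb PTU livers shared PTU and saline without T3, and a hormone-dependent background may explain the pattern as well as shared handling could; neither was tested.

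The third pattern is the block on chromosome 4 with 105 T3-only and 0 PTU-only peaks. All 40 single pairs in the block ranked higher in TRb T3, but pairs that may lie in repeated copies are not clearly separate observations. Random loss of calls near the threshold therefore stays open for the block as a whole. Of the 105 T3-only peaks, 45 scored at or above the median of the TRb T3 list, so those were not weak calls in TRb T3. To test for a tandem array of near-identical copies, the spacing of TRb T3 peaks was counted, and the most frequent spacing between 2 and 20 kb, 5000 to 5250 bp, was 6.58 times as frequent as the mean spacing, against at most 2.77 times in 18 other windows of 1.5 Mb with at least 100 peaks. That spacing need not be the distance between copies, because longer distances were outside the counted range. A looser test, tried first and then replaced, counted peaks with partners at about that spacing and at about double it. It barely separated the block (9.59%) from the same 18 windows (up to 8.55%). In the block, 11 such groups started at a peak with a score of at least 100, and these starts had a median spacing of 81319.5 bp. No value of that longer spacing in other windows is given. The hypothesis is therefore that 1 binding pattern may recur along copies between which reads cannot be placed with certainty, in which case the 105 peaks would not be independent sites; whether T3, or copy number that differs between animals, raised it was not tested.

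The balance of single-list peaks was also set against the rank shift of shared pairs in the same windows. Over 1536 windows with at least 10 single-list peaks and 5 pairs, windows with more T3-only peaks also had shared pairs that ranked higher in TRb T3, with a Spearman correlation of 0.46 (0.46 without the block on chromosome 4), against a highest value of 0.11 (rounded) in 1000 shuffles of the windows. Windows are not independent replicates, and both measures come from the same 2 libraries.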
